A study of Homo sapiens with 13 samples.

How the data were processed

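The data are 13 two-colour hybridisations to Lymphochip spotted cDNA arrays, made from myeloma cell lines that carried a doxycycline-inducible hairpin against IRF4 or against luciferase. Per the labels, the IRF4 hairpin culture was labelled with Cy5 and the luciferase culture with Cy3 on every array, RNA was extracted with Trizol and labelled by reverse transcription, and induced cultures received 20 ng/ml doxycycline. There were no dye swaps, so a gene-specific dye effect stays in each ratio and in the tests against 0, and cancels where arrays are subtracted from one another.

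The authors deposited 1 table of 15246 features by 13 arrays that holds a log ratio per feature and array, taken here as log2. The base of the logarithm is not given in the sources used here, and the values run from -9.78 to 7.51, which as log10 would lie beyond the range of a scanner. The deposited column medians lie between -0.076 and 0.012. The method of normalization, the background correction and the rule by which spots were left blank are not given in the sources used here. Array intensities were not used here, so dye bias that depends on brightness could not be fitted, and how often a feature was measured served as a stand-in for its brightness. Features measured per array ranged from 7140 to 14228, and 221 features had no value on any array. The direction, IRF4 hairpin over control, follows the dyes stated in the labels. The lowest correlation between 2 arrays over all features as deposited was -0.33, between the series 2046 uninduced array and the SKMM1 array, whose conditions differ, and the direction was kept.

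Gene names came from the platform annotation supplied with the table, whose symbols were updated through the gene identifier to a table of human RefSeq genes used for names alone. Of the features, 10169 had 1 gene symbol, 4 had several and 5073 had none; the identifiers of 10128 named features were found in the gene table and 41 kept their older symbol. Features with no single symbol were tested but not named.

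A feature entered the tests if it was measured on at least 10 of the 13 arrays and on at least 2 of the 3 arrays of each KMS12 window, which 6879 features met. Each array was centred on its median over these features, and features of the same gene were averaged per array, which gave 2833 named genes and 1895 unnamed features, 4728 in all. Named genes with 2 or more features numbered 1245. Features of opposite sign at days 4-5 against uninduced are mentioned beside a gene named by the rule below. Apart from IRF4, feature signs were not compared in the other comparisons or for genes named outside the rule. Without centring, the median of all tested features would move by -0.20 on the log2 scale at days 2-3 and by -0.16 at days 4-5 against the uninduced arrays, so all changes are relative to the median gene.

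Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) as 6 group means over all 13 arrays, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Contrasts were KMS12 days 2-3 against uninduced, days 4-5 against uninduced, days 4-5 against days 2-3, H929 against KMS12 days 4-5, and the H929 and uninduced means against 0. Groups with 1 array share the estimated spread. For hairpin 2046 at day 4 in 3 cell lines, a separate fit took 1 value per line (the H929 arrays averaged) and tested the mean against 0. The day 7 array entered the fit but no contrast.

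The 26 gene lists, the named-gene rule, the design and the alternatives were set before the data were examined. The lists cover plasma cell genes, MYC targets, G1/S, G2/M, glycolysis, the citric acid cycle, oxidative phosphorylation, sterol and fatty acid synthesis, the endoplasmic reticulum and unfolded protein response, the ATF4 amino acid response, heat shock, the proteasome, ribosomal proteins, interferon, the IRF family, NF-kB, apoptosis, p53 targets, quiescence, immediate early genes, MHC class I and class II, and markers of earlier B cells, T cells, myeloid cells and erythroid or stromal cells. Of the 374 listed genes that were measured, 15 sat in 2 or more lists. A list median given for a single array was taken over the genes with a value on that array. The 25 lists with at least 5 measured genes were tested against all other genes with camera at its preset correlation of 0.01, beside camera with an estimated correlation and the rotation test fry, whose directional p asks whether the genes of a list move on balance one way. For 2 lists with many missing values the correlation was estimated from pairs of genes, and fry was not run in the fit of all arrays.

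Genes were named by rule: IRF4 first; then, among genes past the threshold with every array on the same side, the 10 most lowered and the 10 most raised for days 4-5 against uninduced and for hairpin 2046 in 3 lines, and 5 and 5 elsewhere; then up to 4 members per list with the smallest p at days 4-5; and where fewer than 5 genes passed, the 5 with the smallest p. Genes named outside this rule are said to be so.

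The culture series was checked as a pairing. Deviations from the group mean correlated within a series by 0.14, 0.18 and 0.19 between uninduced and days 2-3 and by 0.22, 0.16 and 0.19 between uninduced and days 4-5, so the series paired these arrays; between days 2-3 and days 4-5 the values were 0.36, -0.11 and -0.02, and it did not. Hybridisation batches are not given in the sources used here.

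The tests were run on simulated data with the real missing values and the real spread within groups. Cell lines were simulated without any further spread between them, so recovery for the 3 lines is likely overstated. At a simulated log2 change of 1 they recovered 39% of changed genes for days 2-3 (4728 genes tested), 42% for days 4-5 (4728), 65% for the 3 lines (4663) and 55.6% for H929 (4607). At a change of 2 they recovered 84%, 92%, 94.9% and 89.6%. A G2/M list shifted by -0.3 was called in each of these 4 comparisons with 0 of 24 other lists called, with genes simulated as independent.

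Alternatives were values without centring, arrays scaled to a common spread, features on all 13 arrays, no filter on missing values, each feature on its own, a trend and robust prior, array weights, the culture series as a block, a fit of the compared arrays alone, 1332 and 1332b averaged, tests against 0, the KMS12 uninduced mean subtracted, each H929 repeat alone, and each array left out. Centring within classes of how often a feature was measured, and pooled contrasts of all induced arrays, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.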

Results

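Gene expression was measured with spotted cDNA arrays in 3 myeloma cell lines, KMS12, H929 and SKMM1, in which an inducible hairpin against IRF4 was compared with a control hairpin against luciferase (shluc). Myeloma is a cancer of plasma cells, and IRF4 is a transcription factor that plasma cells need. Each of the 13 arrays held RNA of the 2 infected cultures of 1 line, the IRF4 hairpin culture in Cy5 and the control culture in Cy3, so that a log2 ratio below 0 means less mRNA in the cells with the IRF4 hairpin. The KMS12 arrays came in 3 culture series named 1332, 1332b and 2046 in the labels. Each series had 1 uninduced array, 1 array at day 2 or 3 and 1 at day 4 or 5 of doxycycline at 20 ng/ml. This gave 3 uninduced arrays, 3 at days 2-3 and 3 at days 4-5. Series 1332 was taken at days 3 and 5, and series 1332b and 2046 at days 2 and 4. The day within a window thus cannot be told apart from the series, and by the label numbers the series also mix hairpins. Series 1332 also had 1 array at day 7. H929 had 2 repeat arrays and SKMM1 had 1 array, all with hairpin 2046 at day 4. Between 7140 and 14228 of the 15246 features carried a value on an array, and 4728 genes and unnamed features entered the tests. The labels do not say that repeats came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

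IRF4 mRNA was lower in the hairpin culture on all 10 induced arrays and slightly higher on the 3 uninduced arrays. Before induction the IRF4 ratio stood at 118%, 109% and 112% of the control culture in series 1332, 1332b and 2046. At days 2-3 it was 45.2%, 29.1% and 48.8% in the same order, and at days 4-5 it was 66.5%, 64.4% and 59.5%. The day 7 array of series 1332 gave 59%. In the other lines IRF4 was 28.9% and 25.7% of control on the H929 arrays and 24.6% on the SKMM1 array. On the log2 scale the group means were 0.18 ± 0.06 (SD, n = 3) uninduced, -1.32 ± 0.40 (SD, n = 3) at days 2-3, -0.66 ± 0.08 (SD, n = 3) at days 4-5 and -1.88 ± 0.12 (SD, n = 2) in H929. Both tested IRF4 features lay below 0 on all 10 induced arrays that measured them.

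**Figure D1:**
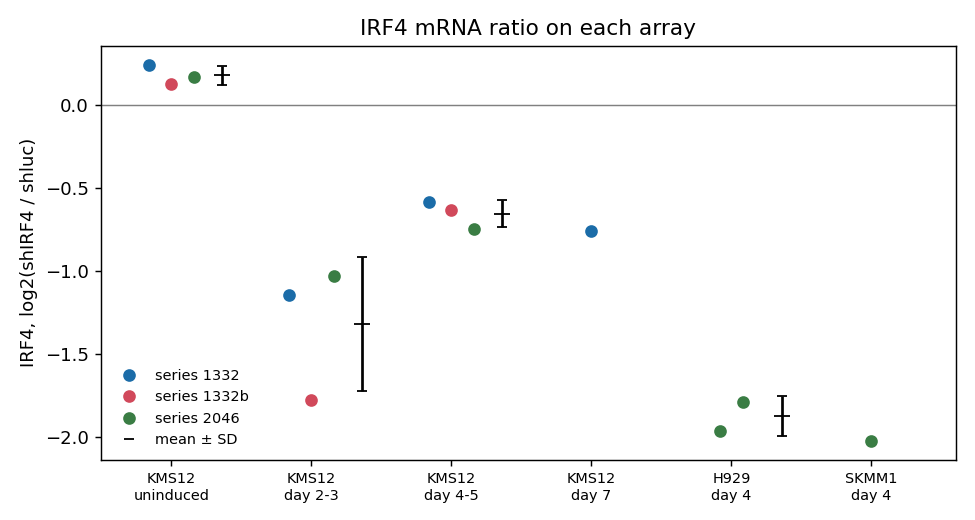
The log2 ratio of IRF4 mRNA in cells with the IRF4 hairpin over cells with the control hairpin (vertical axis) for each of the 13 arrays, by group (horizontal axis). Each point is 1 array coloured by culture series, and black bars give the mean ± SD of groups with 2 or 3 arrays; the 10 induced arrays lie between -2.02 and -0.59 and the uninduced ones between 0.13 and 0.24.

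To ask which transcripts changed first, the KMS12 arrays at days 2-3 were compared with the uninduced arrays. The G2/M genes, which act in mitosis, fell as a list, with a median log2 difference of -0.51 over 29 measured genes, of which 21 lay below 0 (camera adjusted p = 0.0144). The markers of B cells before the plasma cell stage rose as a list, with a median of 0.53 over 18 genes and 16 of them above 0 (camera adjusted p = 0.0299). Both calls were lost when the correlation between genes was estimated (adjusted p = 0.472 with an estimated correlation for each list). Beside the B cell markers, those of other cell types lay above 0 as well without passing, T cell markers with a median of 0.37 (9 of 9 genes), erythroid and stromal markers with 0.45 (8 of 9) and myeloid markers with 0.37 (5 of 6). IRF4 itself was 2.82-fold below its uninduced level (log2 difference -1.50, SE 0.21, 3 arrays against 3, all 3 below every uninduced array), with a limma adjusted p of 0.0764.

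No single gene passed the adjusted threshold at days 2-3: limma called 0 of 4728, although 1222 had an unadjusted p under 0.05 where 236 would be expected by chance, and 504 had an adjusted p under 0.1 (144 higher and 360 lower). The genes with the smallest p, none of which passed, were IRF4, CCNC (cyclin C, log2 difference -2.02, SE 0.31), WDR33 (a factor of mRNA 3' end processing, 1.62, SE 0.25), DNAJC10 (a reductase of the endoplasmic reticulum, -1.50, SE 0.27) and GNG10 (a G protein gamma subunit, -1.33, SE 0.25), each with an adjusted p of 0.0764. The 3 tested features of GNG10 did not share a sign at days 4-5. Adjusted over the list alone, 9 G2/M genes and 0 B cell markers passed, against 0 over all genes. Chosen after their values were seen, the G2/M members furthest from 0 were CENPE (-1.68), a kinetochore motor, and TOP2A (-1.56), the topoisomerase of dividing cells. Adjusted over the list alone, 5 of 11 sterol and fatty acid genes also passed, all lower (6 lower and 1 higher with the culture series as a block), with a list median of -0.74 that did not pass (camera adjusted p = 0.0514). Among the other 22 lists, none of which passed, the endoplasmic reticulum and unfolded protein response list had a median of -0.48, the heat shock list -0.89 and the interferon list 0.35. The rotation test fry called 3 lists, plasma cell genes (median -0.31) and the endoplasmic reticulum list as lower and the B cell markers as higher. It took only genes measured on all 13 arrays, 12 of 16 plasma cell genes, 13 of 17 endoplasmic reticulum genes and 11 of 18 B cell markers. With the culture series as a block fry called 2, keeping the plasma cell list and adding the citric acid cycle as lower, while the endoplasmic reticulum list and the B cell markers no longer passed (fry adjusted p = 0.0611 each). The B cell list did not pass without the series 2046 uninduced array (median 0.48, adjusted p = 0.0633), against 0 (0.23, adjusted p = 0.191), or with arrays centred within classes of how often a feature was measured (0.43, adjusted p = 0.0749). Without the series 2046 array at days 2-3, 653 genes passed, 557 of them lower, and 904 passed when the same arrays were tested against 0 in place of the uninduced arrays.

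At days 4-5 in KMS12, small shifts ran through many gene groups, and 13 of 25 lists passed against the uninduced arrays, 10 lower and 3 higher. The list with the smallest p was that of the amino acid response under the transcription factor ATF4, which fell by a median of 0.38 on the log2 scale over 18 genes, 15 of them below 0 (camera adjusted p = 2.68e-05). The sterol and fatty acid genes fell by a median of 0.40 over 11 genes, 7 of them below 0 (camera adjusted p = 0.0159). Named after their values were seen, FDPS (0.69), STARD4 (0.69), SREBF2 (0.60) and LSS (0.30) lay above 0. MYC and its growth targets fell by 0.23 (19 genes, 17 below 0, adjusted p = 0.000509) and plasma cell genes by 0.17 (16 genes, 11 below 0, adjusted p = 0.0442). The series were uneven. The sterol median went from 0.152 uninduced to -0.775 in series 1332 and from 0.201 to -0.188 in 2046, but from -0.057 to -0.086 in 1332b. Each such median is over the genes with a value on that array, and 6 of the 11 sterol genes had one on every KMS12 array. Part of the unevenness may thus come from which genes were measured, which was not tested. The ATF4 median went from 0.115 to -0.6 in 1332, from 0.004 to -0.226 in 1332b and from 0.21 to -0.09 in 2046. None of the 13 calls held when the correlation between genes was estimated: the lowest adjusted p was 0.312 with an estimated correlation, shared by the ATF4, sterol, MYC and plasma cell lists. The rotation test fry called 1 of 23 lists, plasma cell genes as lower (adjusted p = 0.044), from the 12 of 16 genes measured on all 13 arrays. IRF4 was 1.78-fold below its uninduced level (log2 difference -0.83, SE 0.21, lower on 3 of 3 arrays), with a limma adjusted p of 0.758.

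Within these lists no member passed over all genes at days 4-5, and limma called 0 of 4728 genes, with 282 at an unadjusted p under 0.05 where 236 would be expected by chance. The 5 genes with the smallest p, all with an adjusted p of 0.737 and none passing, were SGK1 (a stress-induced kinase, log2 difference 0.96, SE 0.19), INSIG1 (the protein that holds the sterol sensor in the endoplasmic reticulum, -1.31, SE 0.27), SCD (the enzyme that desaturates stearate, -0.90, SE 0.20), PIM2 (a survival kinase, -1.01, SE 0.22) and SCMH1 (a Polycomb group protein, 0.86, SE 0.20). In the sterol list SQLE (squalene epoxidase) stood at -0.92 and FADS1 (a fatty acid desaturase) at -0.92, and adjusted over the list alone 2 of 11 genes passed, both lower (4 lower and 1 higher with the culture series as a block). In the ATF4 list AARS1 and GARS1, which charge transfer RNAs with alanine and glycine, stood at -1.02 and -0.76. ATF4 itself stood at -0.80 and the amino acid transporter SLC7A5 at -0.65, with 1 of 18 passing when adjusted over the list alone. The fall was uneven within the list. Named after their values were seen, ASNS (-0.10), CEBPB (-0.09), TRIB3 (-0.03) and DDIT3 (-0.015) lay near 0. ATF3 (0.31), SLC1A4 (0.11) and ALDH18A1 (0.11) lay above it. The MYC list held NCL (nucleolin, -1.59, SE 0.78), NPM1 (nucleophosmin, -0.72), TFRC (the transferrin receptor, -0.48) and SHMT2 (-0.38). Among plasma cell genes, ELL2 (an elongation factor for immunoglobulin transcripts) stood at -1.01, TNFRSF17 (the receptor BCMA) at -0.71 and SLAMF7 at -0.59, but MAF at 0.76.

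Lists of the cell cycle and of energy metabolism were lower too at days 4-5, though not in every series. The G2/M median went from 0.167 uninduced to -0.197 in series 1332 and from 0.184 to -0.135 in series 2046, but from -0.05 to 0.068 in series 1332b. The G1/S list fell by a median of 0.17 (17 of 20 genes below 0, camera adjusted p = 0.00569) and the G2/M list by 0.20 (25 of 29 below 0, adjusted p = 0.0039), with MCM4 at -0.71, POLA1 at -0.44, AURKA at -0.48 and PLK1 at -0.42. Glycolytic genes fell by 0.19 (14 of 17 below 0, adjusted p = 0.00569), with GPI at -0.65, ALDOC at -0.52 and HK2 at -0.60 but HK1 at 0.47. Oxidative phosphorylation genes fell by 0.23 (15 of 17, adjusted p = 0.0027), genes of the citric acid cycle by 0.22 (12 of 14, adjusted p = 0.0159) and heat shock genes by 0.30 (6 of 7, adjusted p = 0.0159), with CYCS at -0.70, PDHB at -0.42 and HSPA9 at -0.86. With an estimated correlation their adjusted p values were 0.313 for G1/S, 0.35 for heat shock and the citric acid cycle, and 0.362 for G2/M, glycolysis and oxidative phosphorylation. Without the series 2046 uninduced array the medians were -0.08 for oxidative phosphorylation (adjusted p = 0.0924), -0.14 for heat shock (0.0828), -0.19 for the citric acid cycle (0.0727) and -0.11 for plasma cell genes (0.0813), which no longer passed, and -0.11 for glycolysis, -0.15 for MYC targets, -0.11 for G1/S and -0.13 for G2/M, which did.

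The 3 lists that rose at days 4-5 were all markers of other cell types. The B cell markers rose by a median of 0.28 (13 of 18 above 0, camera adjusted p = 0.0161), with BCL11A at 0.66 and BCL6 at 0.45, while PLCG2 at 0.61 rested on features of opposite sign. Erythroid and stromal markers rose by 0.42 (8 of 9, adjusted p = 0.00569), with PECAM1 at 1.05, FN1 at 0.81 and HBA1 at 0.68, and T cell markers by 0.46 (8 of 9, adjusted p = 0.0401), with LAT at 0.51 and ZAP70 at 0.48. With an estimated correlation their adjusted p values were 0.312, 0.312 and 0.362. Beside them, the B cell list had a median of -0.30 on the uninduced arrays against 0, the T cell list -0.10 and the erythroid and stromal list -0.17. Features measured on few arrays had lower ratios on the series 2046 uninduced array (median -0.41 for those on 1 to 9 arrays, 0.46 for those on all 13). Without that array 6 of the 13 lists passed, all lower, while the B cell (median 0.13, adjusted p = 0.0813), erythroid and stromal (0.35, 0.0813) and T cell (0.34, 0.0828) lists did not. Tested against 0 in place of the uninduced arrays, 5 lists passed at days 4-5. They were the ATF4, sterol, plasma cell and erythroid and stromal lists, and MHC class II as higher (median 0.21, 9 of 9 above 0, camera adjusted p = 0.021). Not passing were B cell markers (median 0.05, adjusted p = 0.986), T cell markers (-0.02, 0.515) and oxidative phosphorylation (-0.04, 0.332). T cell markers had a mean of 0.05 and a test pointing higher. Nor did MYC targets (-0.114, 0.0951), G2/M (-0.13, 0.0951), G1/S (-0.075, 0.114) or glycolysis (-0.119, 0.399) pass.

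The remaining 12 lists did not pass at days 4-5. Their medians were 0.10 for interferon genes, 0.15 for targets of NF-kB, 0.14 for apoptosis genes, 0.14 for p53 targets, 0.16 for quiescence genes, 0.16 for immediate early genes, 0.12 for myeloid markers, 0.03 for MHC class II, -0.09 for MHC class I, -0.09 for the endoplasmic reticulum list, -0.09 for the proteasome and -0.12 for ribosomal proteins. For MHC class II the median was above 0 but the test pointed lower. Values in these lists that stood out by p included IFITM1 (0.52), EIF2AK2 (0.48), LTB (1.09), CCL3 (0.95), BMF (0.96), TP53INP1 (0.97), KLF4 (0.67), DUSP5 (-0.65), NR4A1 (-0.77), HSP90B1 (-0.73) and RPS15A (1.02), none of which passed. Members picked by the same rule lay on the other side in NF-kB (PIM2 -1.01, TNFAIP3 -0.48), apoptosis (CYCS -0.70, FASLG -0.66, BCL2 -0.54) and p53 targets (XPC -0.33). So did RB1 (-0.335) for quiescence, FOS (0.52) and JUN (0.38) for immediate early genes, CRELD2 (0.58) for the endoplasmic reticulum, and RPL8 (-0.30) and RPS3 (-0.31) for ribosomal proteins. None of these passed either. Of the other IRF genes, IRF2 stood at -0.17, IRF3 at -0.10 and IRF9 at 0.01, and this list of 3 measured genes was too small to test.

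**Figure D2:**
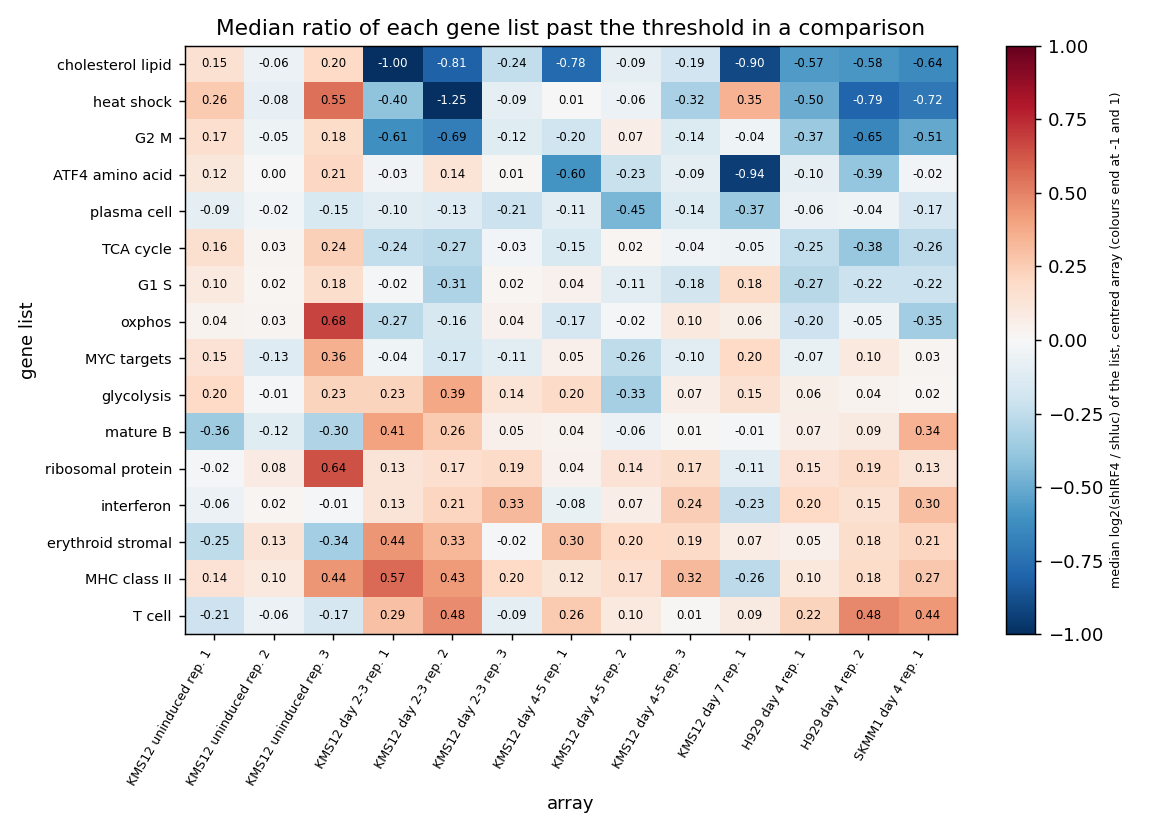
The median log2 ratio (colour and printed value, IRF4 hairpin over control, each array centred on its median) of the 16 gene lists that passed in at least 1 comparison (rows) on each of the 13 arrays (columns). Each median is over the genes of the list with a value on that array, so the genes can differ between arrays. The sterol and fatty acid list lies between -1.002 and -0.086 on the induced arrays, and the oxidative phosphorylation and ribosomal protein lists stand at 0.68 and 0.64 on the third uninduced array.

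The arrays at days 4-5 were then set against those at days 2-3 to follow the course of the response. The glycolytic genes were lower at the later time, by a median of 0.27 on the log2 scale over 17 genes, 13 of them below 0 (the list fell, camera adjusted p = 0.00827; adjusted p = 0.917 with an estimated correlation). GPI differed by -0.89 and ALDOC by -0.71, and adjusted over the list alone 3 glycolytic genes passed, all lower. The other 24 lists did not pass, among them the ATF4 list at -0.31 (adjusted p = 0.0656), G2/M at 0.35 (adjusted p = 0.295) and the endoplasmic reticulum list at 0.29 (adjusted p = 0.295). IRF4 was 0.66 higher on the log2 scale at days 4-5 (SE 0.21), a difference that did not pass (limma adjusted p = 0.197).

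Between the 2 windows fry called 0 of 23 lists and limma 0 of 4728 genes, with 857 at an unadjusted p under 0.05. The smallest p belonged to TMEM167A (1.93), WDR36 (a ribosome assembly factor, 1.58), GNG10 (1.19), POR (the reductase that serves cytochrome P450 enzymes, -0.85) and RPS6KB1 (the S6 kinase, 0.90), each with an adjusted p of 0.176, so none passed. Without the series 2046 array at days 2-3, 360 genes passed, 328 of them higher at days 4-5. Without the series 1332b array at days 4-5 the median of the glycolytic list was -0.10 and its adjusted p 0.164.

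Hairpin 2046 was used in all 3 cell lines, which allowed the response at day 4 to be compared across lines with each line as 1 replicate. The G2/M list fell across KMS12, H929 and SKMM1 (median log2 ratio -0.40 over 28 genes, 22 below 0, camera adjusted p = 0.00396), and the heat shock list fell (-0.57, 7 of 7 below 0, adjusted p = 0.0142). The interferon list rose, with a median of 0.22 over 19 genes and 14 of them above 0 (adjusted p = 0.0142). Beside it T cell markers stood at 0.31 (8 of 9 above 0), MHC class II at 0.20 (8 of 9), myeloid markers at 0.23 (4 of 6) and erythroid and stromal markers at 0.19 (6 of 9), none of which passed. With an estimated correlation none of the 3 held (adjusted p = 0.576 with an estimated correlation for each), and fry called 0 of 25 lists. IRF4 averaged -1.55 (SE 0.28), at -0.75 in KMS12, -1.88 in H929 and -2.02 in SKMM1.

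No single gene passed across the 3 lines (limma, 0 of 4663 called, 773 at an unadjusted p under 0.05, 233 expected by chance). The smallest p belonged to HSP90B1 (an endoplasmic reticulum chaperone, log2 ratio -1.27), TBC1D14 (-0.999), NCL (nucleolin, -1.75), SRP72 (a part of the signal recognition particle, -1.10) and HSPA9 (a mitochondrial chaperone, -1.003), each with an adjusted p of 0.27. Adjusted over the list alone, 5 genes of the endoplasmic reticulum list passed as lower and 1 as higher, with HSPA5 at -0.98 and PDIA4 at -0.71, and 4 heat shock genes and 4 sterol genes passed as lower, with SQLE at -0.95 and FADS1 at -0.95. The interferon list held ISG15 (0.83), EIF2AK2 (0.68) and IFITM1 (0.63), of which none passed even adjusted over the list alone. The interferon list did not pass without KMS12 (adjusted p = 0.0846) or with features on all 13 arrays (0.0561), nor the heat shock list without KMS12 (0.0846) or with a trend and robust prior (0.0756). Without KMS12, 737 genes passed, 524 of them lower. No uninduced arrays of H929 or SKMM1 were analysed here. Gene-specific dye bias and any difference between the cultures before induction therefore remain in these ratios.

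In H929, 195 of 4607 genes and unnamed features differed from 0 at day 4, 142 below and 53 above (limma, 1176 at an unadjusted p under 0.05). No uninduced H929 array was analysed here. Dye bias and any difference between the cultures before induction therefore remain, and fell and rose mean below and above 0. The count is unlike the 0 called in KMS12 against uninduced arrays, where 904 passed at days 2-3 when tested against 0. Of the named genes 94 fell and 15 rose. IRF4 fell by 1.88 on the log2 scale (SE 0.19, 2 of 2 arrays, adjusted p = 0.00198). Among the 5 most lowered, LMAN1, a cargo receptor between the endoplasmic reticulum and the Golgi apparatus, fell by 1.92 (SE 0.30, 2 of 2 arrays, adjusted p = 0.0201), and DYRK4, a protein kinase, fell by 2.03 (SE 0.49, with -0.52 and -3.54 on the 2 arrays). RAB39B (-2.46, SE 0.47) and BATF (a transcription factor of B and T cells, -1.93, SE 0.24) passed as well but were measured on 1 of the 2 H929 arrays. The most raised were WDR33 (1.25, SE 0.19), the interferon-induced ISG15 (1.05, SE 0.21), the melanocyte antigen gene MLANA (1.01, SE 0.20), PARP14 (1.00, SE 0.23) and UCP2 (0.94, SE 0.19), each on 2 of 2 arrays.

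Several of the H929 changes fell into the lists. The sterol and endoplasmic reticulum lists did not pass camera as lists (medians -0.45 and -0.24, camera adjusted p = 0.154 and 0.224). With an estimated correlation the adjusted p was 0.536 for each. Some of their members did pass. In the sterol and fatty acid list 3 of 10 genes fell, SQLE by 1.20 (SE 0.29), FADS1 by 1.42 (SE 0.31) and SCD by 0.79 (SE 0.17), with the same 3 counted adjusted over the list alone. In the endoplasmic reticulum list HSP90B1 fell by 1.42 (SE 0.33), HSPA5 by 1.27 (SE 0.30) and PDIA4 by 0.86 (SE 0.20), and 5 of 17 passed as lower adjusted over the list alone. The G2/M list fell, with a median of -0.55 and 20 of 28 genes below 0 (camera adjusted p = 0.000324; adjusted p = 0.536 with an estimated correlation). Its members CCNB1 (-0.68) and BUB1 (-1.71), named after their values were seen, passed over all genes and 15 passed adjusted over the list alone. T cell markers rose as a list (median 0.37, 9 of 9 above 0, adjusted p = 0.0493; adjusted p = 0.536 with an estimated correlation). Fry called 3 of 23 lists, all lower: plasma cell genes, the endoplasmic reticulum list and G2/M. In lists that did not pass camera, members that fell, also named after their values were seen, were PCNA (-1.35) and PRIM1 (-1.19) in G1/S (14 of 19 below 0) and MTHFD2 (-1.53) and VEGFA (-1.01) in the ATF4 list (14 of 18 below 0). XBP1 (-0.83), named likewise, fell among plasma cell genes (9 of 16 below 0). LDHA (-1.19), EIF4E (-1.25) and MCL1 (-1.23), also named after their values were seen, fell. Most of their lists lay above 0, with 11 of 17 glycolytic genes, 10 of 18 MYC targets (3 higher and 2 lower adjusted over the list alone) and 15 of 24 apoptosis genes. The T cell list did not pass without the second repeat (median 0.22, adjusted p = 0.247), with arrays scaled to a common spread (adjusted p = 0.0562) or with centring within classes of how often a feature was measured (0.0654). The count of genes fell from 195 to 37 with arrays scaled to a common spread, and it fell with either repeat alone. Subtracting the KMS12 uninduced mean gave 807. That mean came from another cell line and was taken as fixed. Its own error is left out, so the count of 807 is too lenient.

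**Figure D3:**
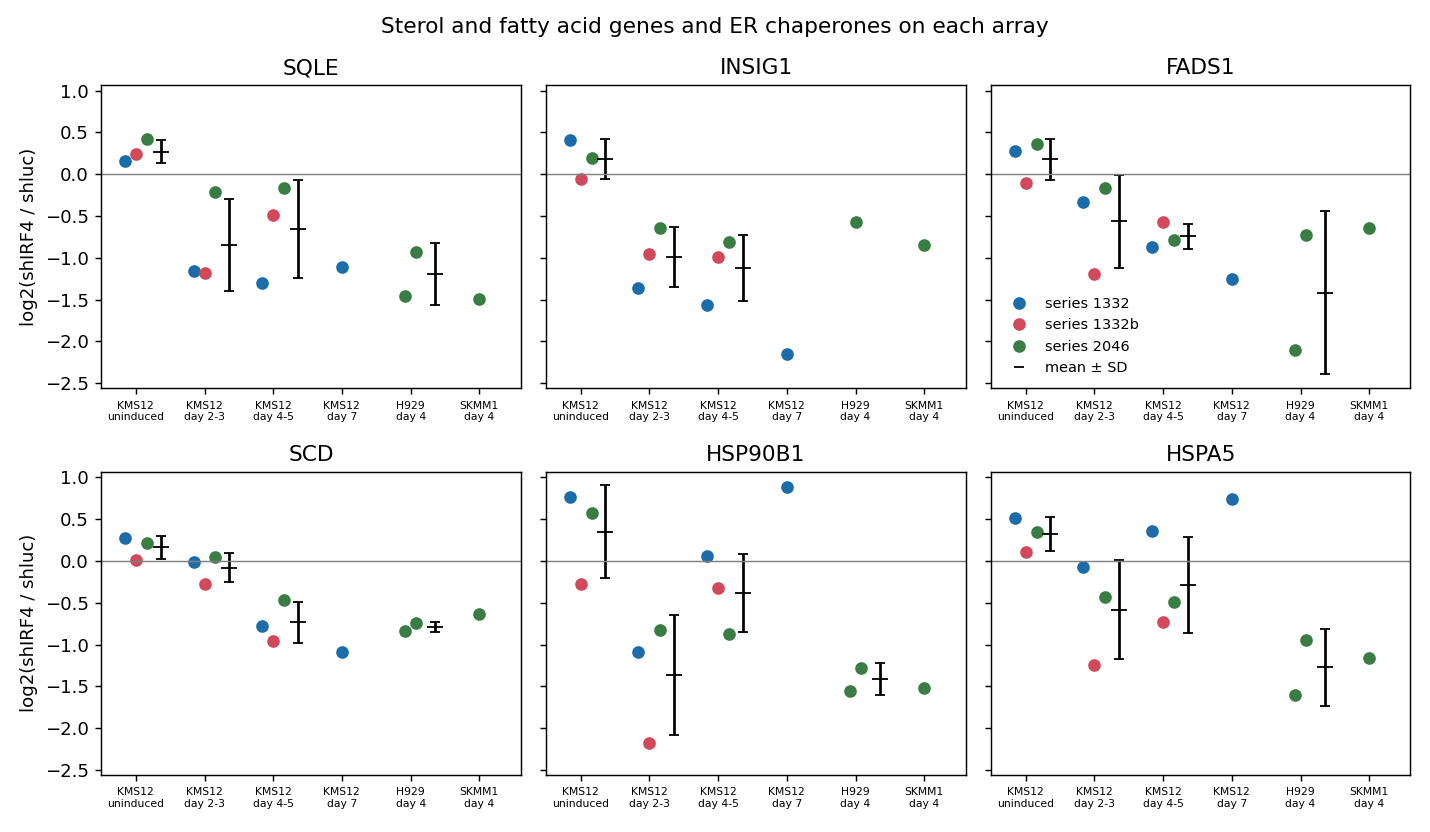
The log2 ratio (vertical axis, IRF4 hairpin over control) of 4 sterol and fatty acid genes and 2 endoplasmic reticulum chaperones on each array that measured them, by group (horizontal axis). Points are arrays coloured by culture series and black bars give mean ± SD; SQLE lies below 0 on all 10 induced arrays (-1.49 to -0.17), while HSP90B1 stands at 0.89 on the day 7 array.

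The ratios of H929 at day 4 were also compared directly with those of KMS12 at days 4-5. Each ratio is taken within 1 line, so a difference here is not one of expression level between the lines. The H929 arrays had hairpin 2046 at day 4, and among the KMS12 arrays only that of series 2046 matches them. The others came from series 1332 at day 5 and 1332b at day 4, so cell line is partly mixed with hairpin and day. No uninduced arrays were subtracted, so differences between the cultures before induction remain too. SERPINA1, the gene of alpha-1 antitrypsin, was lower in H929, with a log2 difference of -1.77 (limma adjusted p = 0.0126), with ratios of -1.24 and -1.42 on the H929 arrays and 0.37, 0.57 and 0.38 on the KMS12 arrays. BATF had a difference of -2.39 (adjusted p = 0.0181), from 1 H929 array at -1.93 against 0.22, 0.64 and 0.50 in KMS12, so that the spread between H929 arrays was not measured for it. These were the 2 of 4607 that passed, both lower in H929, with 781 at an unadjusted p under 0.05. H1-2, a linker histone (-1.34), OSBPL11 (-1.31) and THOP1 (1.31) came next, each with an adjusted p of 0.0549, and did not pass. The G2/M list was lower in H929 (median difference -0.38, 21 of 28 genes below 0, camera adjusted p = 0.0406; adjusted p = 0.963 with an estimated correlation), and fry called 0 lists. The IRF4 difference was -1.22 (SE 0.24, adjusted p = 0.0682). Neither gene passed when either the series 1332b or the series 2046 array at days 4-5 was left out, when arrays were scaled to a common spread or with no filter on missing values, where BATF stood at -0.49. SERPINA1 did not pass without the second H929 array (adjusted p = 0.07), which is the 1 array that measured BATF, and the G2/M list did not pass in any refit with 1 array left out.

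The uninduced KMS12 arrays gave the background, the ratio of the cultures before the hairpin was switched on. Ribosomal protein genes were higher in the hairpin culture than in the control culture as a list (median 0.25, 23 of 27 above 0, camera adjusted p = 9.42e-05), as were MHC class II (0.24), oxidative phosphorylation (0.18), glycolysis (0.18) and MYC targets (0.14), while B cell markers were lower (-0.30, 15 of 18 below 0, adjusted p = 0.00543). With an estimated correlation none of these 6 lists held (adjusted p = 0.558 with an estimated correlation for each), and fry called 0 lists. Limma called 0 of 4728 genes, with 379 at an unadjusted p under 0.05, and the genes with the smallest p, none passing, were CDC42BPA (-1.15), ZNF134 (-0.80), EPB41 (-0.76), CTBP1 (0.51) and PANK3 (-0.91). Without the series 2046 array 0 lists passed.

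The 3 culture series were compared across genes, each with its own uninduced array subtracted. At days 2-3 the genome-wide differences correlated with r = 0.65 between 1332 and 1332b, 0.55 between 1332 and 2046 and 0.37 between 1332b and 2046. At days 4-5 the same pairs gave 0.05, 0.35 and 0.11. Between the days 2-3 response of 1 series and the days 4-5 response of another, r ranged from -0.20 to 0.42 with a mean of 0.20 over 6 pairs. These correlations run across genes, which are not independent replicates, and no p-value was computed. On single arrays the ratios of H929 and SKMM1 correlated at 0.64 and 0.67, and, against the first and second H929 repeat, those of the KMS12 arrays at days 2-3 at 0.51 and 0.64 (series 1332b), 0.37 and 0.43 (series 1332) and 0.21 and 0.20 (series 2046). The series 2046 array of KMS12 at day 4 correlated at 0.12 and 0.08 with the H929 arrays and at 0.12 with SKMM1.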

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

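Of the tests in this part, 4 were chosen only after the result was seen: that on fewer cells with the knockdown, that on the extent of the IRF4 reduction, and the 2 on a difference already present between the uninduced cultures.

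A difference in ratio between time windows or cell lines drew attention to 4 results. The ratio of IRF4 hairpin over control for SERPINA1 was lower in H929 at day 4 than in KMS12 at days 4-5 (log2 difference -1.771). BATF differed by -2.385 but was measured on 1 of the 2 H929 arrays, so that its p takes the spread from other groups. The ratios of the G2/M list were lower in H929 than in KMS12 (median difference -0.383, camera adjusted p = 0.963 with an estimated correlation). That call was lost with any 1 array left out. In these comparisons with H929, cell line is partly mixed with hairpin and day, and differences between the cultures before induction remain. In KMS12 the glycolytic list was lower at days 4-5 than at days 2-3 (median difference -0.274; adjusted p = 0.917 with an estimated correlation), a call lost without the series 1332b array at days 4-5. Outside the contrasts, the single day 7 array of series 1332 held an IRF4 log2 ratio of -0.76, further from 0 than on any uninduced array.

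IRF4 itself stood less far below control at days 4-5 than at days 2-3 in KMS12, with a log2 difference of 0.66 (SE 0.21) that did not pass. A smaller spread of all ratios on the later arrays could account for part of this: with arrays scaled to a common spread the difference was 0.332 (SE 0.19), between 1 and 2 standard errors from 0, so that this explanation cannot be told apart. Fewer cells with the knockdown at the later time, with all changes shrinking alike, would leave no list further from 0 at days 4-5. The count of such lists with an adjusted p under 0.05 for the window difference was 0, the nearest being the ATF4 list at 0.0656, and a test with 3 arrays a window excludes nothing. A difference in the days after induction, which the design names, stays open as well.

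The KMS12 arrays at days 2-3 in series 1332 and 1332b, the H929 arrays and the SKMM1 array scored high on 1 component of the ratios, which held 43.4% of the variance over 2495 genes without IRF4. Over the 10 induced arrays this component rose as IRF4 fell (Pearson r = -0.86, permutation p = 0.00435; Spearman rho = -0.82, permutation p = 0.00587; r = -0.83 without the SKMM1 array and the second H929 array; adjusted p = 0.0107 over 4 relations). Within the 7 induced KMS12 arrays r was -0.91 (permutation p = 0.00536; rho = -0.75, p = 0.0663; adjusted p = 0.0107) but -0.50 without the series 1332 and 1332b arrays at days 2-3, on which it rests. The number of spots kept per array might also shape the component, and its r of -0.21 over the 10 arrays (permutation p = 0.555; rho = 0.02, p = 0.973; r = 0.39 without the series 1332b and 2046 arrays at days 4-5; adjusted p = 0.74), with -0.10 within KMS12 (permutation p = 0.806; rho = -0.14, p = 0.783; r = 0.57 without the series 1332 array at days 2-3 and the series 1332b array at days 4-5; adjusted p = 0.806), cannot be told apart from a moderate relation with so few arrays. The spread of all tested ratios on an array may also move IRF4 and the component together, which was not tested and cannot be told apart. Its median absolute deviation was 0.634 and 0.553 on the series 1332b and 1332 arrays at days 2-3. It was 0.595 on SKMM1, 0.538 and 0.431 on H929 repeats 2 and 1, and 0.348, 0.357 and 0.32 at days 4-5. The series 2046 array at days 2-3 had 0.331, and the day 7 array 0.475 with a score of -13.5. These permutations treat the arrays as exchangeable, although several share a culture series and 2 are H929 repeats. That the extent of the IRF4 reduction sets the size of the shared response remains a hypothesis, found and tested on the same arrays.

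Of the 13 lists that passed in KMS12 at days 4-5, 4 still passed in the same direction against 0 (ATF4, sterol and fatty acid, plasma cell, and erythroid and stromal). The tables argue most against a difference already present between the uninduced cultures for the ATF4 and sterol lists, whose uninduced medians lay on the other side of 0 (0.12 and 0.14) and whose calls held without the series 2046 uninduced array (adjusted p = 0.000372 and 0.0404) and with arrays centred within classes of how often a feature was measured (6.47e-05 and 0.00721); the erythroid and stromal list (uninduced -0.17) and the plasma cell list (-0.12, on the same side) lost their calls without that array. In series 1332b, though, the sterol median was -0.057 uninduced and -0.086 at days 4-5, each over the genes with a value on that array. None of the 4 lists passed against 0 with an estimated correlation (lowest camera adjusted p = 0.452). A difference already present between the uninduced cultures therefore cannot be told apart for them. For 7 of the 9 others the uninduced median lay further from 0 than the day 4-5 median, which passing against the uninduced arrays but not against 0 largely fixes, so that this decides nothing. A bias of the ratios with brightness, read from how often a feature was measured, cannot be told apart: 9 of the 13 lists still passed with arrays centred within classes of that measure, the plasma cell, B cell, T cell and heat shock lists did not, and an effect of the hairpin stays open beside both.

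Regrouping the same 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. At days 2-3, 1 split, the real one, reached 1222 genes at an unadjusted p under 0.05 (highest other 736), and 4 splits reached its 2 lists (highest other 4). At days 4-5, 3 splits reached 282 genes (highest other 415) and 1, the real one, reached 13 lists (highest other 9). Between the windows, 2 splits reached 857 genes (highest other 909) and 4 reached 1 list (highest other 3). Among splits that part all 3 culture series, as the real ones do, the other counts of genes were 269, 154 and 56 at days 2-3 and 71, 165 and 93 at days 4-5. Their counts of lists were 3, 3 and 0 at days 2-3, against 2 in the real split, and 1, 1 and 0 at days 4-5, against 13.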

How the results depend on the processing

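Of the alternatives in this part, 3 were chosen only after the data were seen: centring within classes of how often a feature was measured, and the pooled contrasts of 7 and of 10 induced arrays. Of 115 refits of the 12 calls of a named gene 73 kept the call and 42 lost it; of 460 refits of 33 gene values that had not passed 49 newly passed. Of 398 refits of a called list 307 kept the call, 90 lost it and 1 reversed. In 1 the direction turned: the B cell list at days 4-5 against 0 had a median of 0.049 with a test pointing lower (adjusted p = 0.986). Signal over background could not be assessed, since array intensities were not used here, and the cause of the changes below was not tested except where fewer arrays or genes enter. A lone array left in a group is assumed to vary like the others. Where the KMS12 uninduced mean was subtracted, it was taken as fixed. Its own error is left out there, so those tests are too lenient, and for H929 and SKMM1 it came from another cell line.

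Genes passing, as main count then alternatives. Alternatives whose count equalled or came near the main count are left out here, and in the next paragraph save for days 4-5. Days 2-3 (0): 339 without centring (12 up, 327 down), 2 scaled to a common spread, 170 with features on all 13 arrays, 3 with no filter, 393 with array weights, 904 against 0, and 0 to 653 with 1 array left out (653 without series 2046 at days 2-3; 1 without series 1332b uninduced or at days 2-3). Days 4-5 (0): 4 against 0, and 0 to 1 with 1 array left out (1 without series 1332b uninduced). Days 4-5 against 2-3 (0): 1 with no filter, and 0 to 360 (360 without series 2046 and 1 without series 1332b at days 2-3). Day 4 in 3 lines (0): 0 to 737 with 1 line left out (737 without KMS12). H929 (53 up, 142 down): 37 scaled (1 up, 36 down), 383 with features on all 13 arrays, 5 with no filter, 351 by feature, 90 with a trend and robust prior, 784 with array weights, 807 with the KMS12 uninduced mean subtracted (185 shared), and 5 to 19 (5 without repeat 2, 19 without repeat 1). Uninduced (0): 0 to 1 (1 without series 1332b). H929 against KMS12 (2): 0 scaled, 60 with features on all 13 arrays, 1 with no filter, 6 by feature, 8 with a trend and robust prior, 108 with array weights, 14 with class centring, and 0 to 4 (0 without series 1332b or 2046 at days 4-5, 4 without either H929 array, sharing 0 without repeat 2 and 2 without repeat 1; 0 shared with no filter).

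Lists passing. With an estimated correlation 0 passed in each of the 7 comparisons. Days 2-3 (2): 0 with features on all 13 arrays, 9 with no filter, 6 with array weights, 4 with 1332 and 1332b averaged, 4 against 0, 1 with class centring, and 1 to 8 with 1 array left out (8 without series 1332b uninduced, 1 without series 2046 uninduced, 4 without series 1332 or 2046 at days 2-3). Days 4-5 (13): 4 with features on all 13 arrays, 5 against 0, 9 with class centring, 10 without centring and 16 with no filter. The count was 11 scaled, with a trend and robust prior, with array weights or with the compared arrays alone. With 1332 and 1332b averaged it was 13, of which 11 were shared. With 1 array left out it was 6 to 13 (6 without series 2046 uninduced). Days 4-5 against 2-3 (1): 2 scaled, 0 with features on all 13 arrays, and 0 to 2 (0 without series 1332b at days 4-5, 2 without series 1332 at days 2-3 or series 2046 at days 4-5). Day 4 in 3 lines (3): 8 with the KMS12 uninduced mean subtracted, and 1 to 4 (1 without KMS12). H929 (2): 1 scaled, 1 with features on all 13 arrays, 7 with no filter, 4 with the uninduced mean subtracted, 1 with class centring, and 1 to 3 (1 without repeat 2), with the T cell list lost in each case of 1, or too small to test with features on all 13 arrays. Uninduced (6): 1 with features on all 13 arrays, 13 with no filter, and 0 to 7 (0 without series 2046). H929 against KMS12 (1): 0 without centring, scaled, with features on all 13 arrays, with a trend and robust prior and with class centring, and 0 to 0 with any 1 array left out.

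With the culture series as a block, 0 genes passed in each of the 3 KMS12 comparisons (1273, 341 and 956 at an unadjusted p under 0.05) and camera called the same 2, 13 and 1 lists as without it. Of the fry calls at days 2-3 the block kept plasma cell genes, lost the endoplasmic reticulum and B cell lists and added the citric acid cycle; the pairing changed no other call of a list over all lists. Counts adjusted over the list alone moved with the block, among others: at days 2-3 plasma cell genes from 1 higher and 4 lower to 0, NF-kB targets from 3 to 0 higher, G2/M from 9 to 7 lower and sterol genes from 5 lower to 6 lower and 1 higher. At days 4-5 sterol genes from 2 lower to 4 lower and 1 higher, MYC targets and heat shock genes from 0 to 1 lower each and ribosomal proteins from 1 to 0 higher. Between the windows glycolysis from 3 to 4 lower. Pooled, 7 induced KMS12 arrays against 3 with the block gave 0 genes (506 at an unadjusted p under 0.05, IRF4 -1.15, SE 0.25), and 10 induced arrays against 3 gave 0 (667, IRF4 -1.42, SE 0.32).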

Other observations

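The genes of this part were chosen after their values were seen, and the pooled test of 10 induced arrays was chosen only after the data were seen.

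Across the 3 lines, some genes separated every induced array from every uninduced KMS12 array. Of 2496 genes and unnamed features measured on all 13 arrays, 55 lay lower on all 10 induced arrays than on all 3 uninduced ones and 19 lay higher, where 8.7 each would arise if arrays were exchangeable; the 13 arrays share series and lines and are not. IRF4 had the largest mean difference among named genes (-1.42), followed by MTHFD2, a mitochondrial enzyme of folate metabolism (-1.33), and SQLE (-1.22). Next came PPP1R2 (-1.16), RAD21 (-1.16) and OLA1 (-1.10). Lower as well, among others, were NFIL3, a leucine zipper repressor (-1.09), FADS1 (-1.04), GARS1 (-0.93), TNFRSF17 (-0.72) and ATF4 (-0.71). PRDM1, the transcription factor that directs plasma cell development, stood at -0.70. Among the higher genes were GEM (0.95), SCMH1 (0.75), HSH2D (0.64), BCL11A (0.61), ZAP70 (0.56) and BCL6 (0.52), the last a repressor of PRDM1 in germinal centre B cells. The gap between induced and uninduced arrays was only 0.027 for BCL6, 0.054 for PRDM1 and 0.034 for TNFRSF17. None of the genes passed in the contrast of 10 induced against 3 uninduced arrays, in which limma called 0 of 4728 (667 at an unadjusted p under 0.05).

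The single day 7 array of series 1332 is in no contrast. Its list medians, over the genes with a value on it, were -0.94 for the ATF4 list and -0.90 for the sterol and fatty acid list. Plasma cell genes had -0.37, and INSIG1 stood at -2.15. The endoplasmic reticulum list stood at 0.42 on this array and the heat shock list at 0.35. The uninduced array of the same series gave 0.114 and 0.262 in that order. On the day 7 array HSP90B1 stood at 0.89, PDIA4 at 0.94 and HSPA5 at 0.74. These 3 genes lay below 0 on average at days 2-3 (-1.36, -0.47 and -0.58) and in H929 (-1.42, -0.86 and -1.27).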
